A study of Homo sapiens with 6 samples.

How the data were processed

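The series measured U2OS osteosarcoma cells with iCLIP of FLAG-tagged TIRR (2 libraries of untreated and 2 of irradiated cells) and with RNA-seq of wild-type cells (1 untreated and 1 irradiated library). Irradiated cells received 5 Gy of X-rays and recovered for 4 h, per the labels, while the series' design text speaks of gamma radiation for RNA-seq. The series' design text describes ultraviolet crosslinking, partial RNA digestion and recovery of the complexes with FLAG antibodies, and it names empty-vector cells, which were not used here. The labels do not say whether replicates are separate cultures, so each p-value measures the spread between these libraries, which may be technical.

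The deposited tables give 1 line per gene with at least 1 cDNA, and 1 further line for intergenic counts. The authors deposited whole-number cDNA counts per gene without scaling, per the file headers and the values. They also deposited each gene's percent of all cDNA in the library, intergenic counts included, per the file headers. A length in bases accompanies each gene. The genome build is hg38, per the submitters' processing notes, which also name kallisto 0.44.0 for the RNA-seq libraries. How kallisto relates to the gene tables, the aligner, the removal of duplicates, the annotation release and the strand setting are not given in the sources used here. Of the gene identifiers, 99.9% (iCLIP) and 99.7% (RNA-seq) matched the gene name table used. Gene positions came from a RefSeq table of assembly GRCh38.p14, which holds no strand.

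The iCLIP libraries held 583192 to 1155052 counts and listed 18715 to 22029 genes each, and the RNA-seq libraries held 23401311 and 23407174 counts. The intergenic counts were left out of library sizes and tests. Shares of a single library carry exact Clopper-Pearson 95% intervals, and ratios of 2 RNA-seq libraries carry exact conditional 95% intervals. For genes with 3 or fewer counts in a group, the ratio of the summed counts is given with such an interval in place of the fitted change. All these intervals cover counting error only. The replicate libraries differed by more than counting error (chi-square over degrees of freedom 1.42 for the untreated and 1.87 for the irradiated pair).

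The iCLIP comparison of irradiated with untreated libraries used the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, the default filterByExpr filter and Benjamini-Hochberg adjustment at 0.05, two-sided. Values called CPM are counts per 1e+06 of the TMM-scaled library size. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The edgeR and camera steps were tested on simulated counts for the iCLIP comparison, with 9204 genes of which 200 were changed. They recovered 70% of 2-fold rises, 100% of 4-fold rises, 42.2% of 2-fold falls and 82.6% of 4-fold falls, and 7 of the 149 calls were unchanged genes. With no change simulated, no gene was called. Every simulated gene had the same coefficient of variation, 0.1, so these counts cannot show how often genes with more uneven replicates are called falsely. In the self-test of the RNA-seq list percentiles, 3 of 20 unshifted lists fell outside the 2.5 to 97.5 percentiles, more often than the nominal 5%, and the shifted list lay at 100.

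For RNA-seq, a gene passed the size rule with at least 100 counts in the library with more, a TMM-scaled ratio of at least 2-fold and a 95% interval wholly beyond 1.5-fold. A list's median log2 ratio was set among 10000 random lists of the same size matched on expression in 20 bins, over genes with at least 20 counts in both libraries together, as a description of these libraries. The iCLIP share was divided by the RNA-seq share in untreated cells, with a prior count of 0.5, and lists were matched on RNA-seq level and gene length. This used genes with at least 50 RNA-seq counts that were listed in any iCLIP library, the irradiated ones included. The changes in both assays were correlated across genes with 100000 permutations, two-sided, as 1 family of 2 relations (Spearman and Pearson). These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

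The groups, the tests, the 27 gene lists and the rule for the genes named in the text were chosen before the data were examined. The rule names NEAT1, MALAT1, NUDT16L1 and TP53BP1, the 10 largest rises and falls among called iCLIP genes whose groups do not overlap, the 10 highest iCLIP shares, and the 12 largest RNA-seq rises and falls past the size rule. It also names the 10 highest and lowest ratios of iCLIP to RNA-seq. From each list described it takes up to 4 members with the most counts plus members past the threshold, 6 at most, and clone identifiers without an approved symbol are counted rather than named. Some results that the rule covers are not reported here. In RNA-seq the lists included markers of epithelial, haematopoietic and endothelial cells, to look for RNA of other cell types. Only their change between the libraries is reported, which cannot show whether such RNA was present in both.

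Alternatives were other scalings (RLE size factors and library totals), no filter and a stricter filter on low counts, removal of short multicopy RNAs, a replicate block, DESeq2 1.42.0 and the removal of each library in turn. For RNA-seq they were other scalings and count minimums and lists matched on length as well, and for the ratios another prior count, the irradiated libraries and the removal of each untreated iCLIP library, each with its own random lists. Thinning all iCLIP libraries to the smallest one and leaving out RNA-seq genes that overlap another gene or have no known position were added after seeing the data.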

Results

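U2OS, a human osteosarcoma cell line, was measured with 2 assays, before and after a dose of 5 Gy of X-rays with 4 h of recovery, per the labels (the design text speaks of gamma radiation for RNA-seq, so the source of radiation may differ between the assays). In iCLIP, ultraviolet light fixes RNA to the protein it touches, and the RNA that came down with FLAG-tagged TIRR was sequenced from 2 libraries of untreated and 2 of irradiated cells. TIRR is the product of NUDT16L1 and binds 53BP1, a DNA double-strand break repair protein made from TP53BP1. RNA-seq of wild-type U2OS cells had 1 untreated and 1 irradiated library, so its values have no replicate check. The untreated iCLIP libraries held 1126087 and 1155052 counts and the irradiated ones 583192 and 962372. Of these, 781997, 799709, 400723 and 664777 counts lay on genes. The RNA-seq libraries held 23401311 counts (untreated) and 23407174 counts (irradiated), with 13015406 and 13023903 on genes. Cells with an empty vector were not analysed here, so no background could be subtracted from the iCLIP values.

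The first question was which RNAs the TIRR libraries hold. NEAT1, the long noncoding RNA around which nuclear paraspeckles form, took the largest share of the gene counts in untreated cells, 2.58% ± 0.158 (SD, n = 2). It was followed by FAM95A with 1.42% ± 0.0728, MALAT1, a long noncoding RNA of nuclear speckles, with 1.39% ± 0.0131, and NTM, which encodes a neural cell adhesion protein, with 0.827% ± 0.0181. MT-RNR2, the mitochondrial 16S ribosomal RNA, had 0.634% ± 0.239, and its replicates differed widely. OSBPL10, a lipid transfer protein gene, had 0.267% ± 0.0175 and the long noncoding RNA PVT1 had 0.261% ± 0.0129 (SD, n = 2 each). Of the 10 genes with the highest share, 2 carry clone identifiers only. Counts per kb of annotated gene were ranked over 9328 genes of at least 200 bases with 20 or more summed untreated counts. Shorter RNAs were not ranked. MALAT1 had 1252 counts per kb in the mean of the untreated libraries, rank 2, and NEAT1 had 915, rank 4. The median of the ranked genes was 0.702 counts per kb.

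The next question was whether irradiation changed the amount of NEAT1 recovered with TIRR. NEAT1 (ENSG00000245532, chromosome 11, 65422798 to 65445540, a long noncoding RNA gene) rose from 2.58% ± 0.158 to 3.37% ± 0.0392 of the gene counts (SD, n = 2 each). The single libraries had 2.69% (exact Clopper-Pearson 95% interval 2.66 to 2.73) and 2.47% (2.44 to 2.504) before, and 3.39% (3.34 to 3.45) and 3.34% (3.29 to 3.38) after the dose. The log2 fold change was 0.45 with a standard error of 0.08 (1.37-fold, edgeR adjusted p = 0.00271), and both irradiated libraries lay above both untreated ones. MALAT1, its neighbour on the same chromosome arm, had a log2 fold change of 0.03 ± 0.09 (SE, edgeR adjusted p = 0.919), which became -0.04 when scaled by library totals and -0.01 with no filter on low counts. In CPM both irradiated libraries also lay above both untreated ones for MALAT1, so this separation alone does not set NEAT1 apart. In RNA-seq NEAT1 had 4309 counts before and 3801 after irradiation, a ratio of 0.872 (95% counting interval 0.835 to 0.911). MALAT1 had 2248 and 2392 RNA-seq counts, a ratio of 1.05 (0.993 to 1.12). With DESeq2 in place of edgeR the log2 fold change of NEAT1 was again 0.45 but its adjusted p was 0.0742, and in edgeR with a replicate block it was 0.252.

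**Figure D1:**
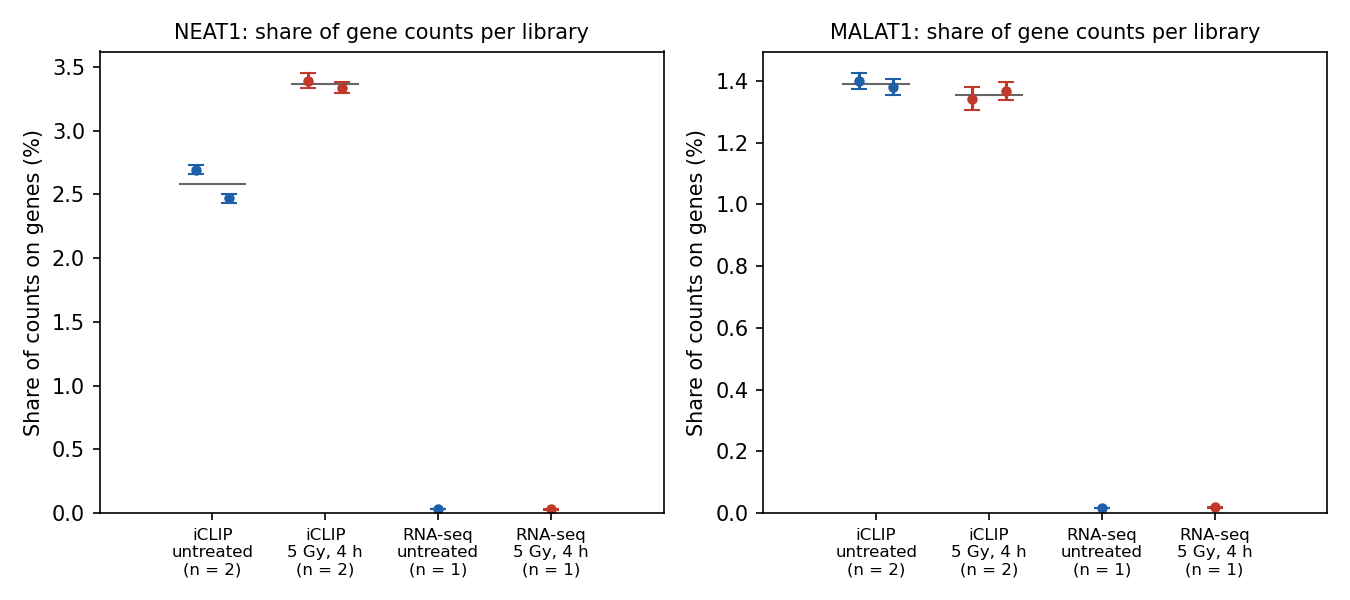
Share of the counts on genes (percent) taken by NEAT1 and MALAT1 in each library, with exact 95% intervals for counting error and grey lines at the means of 2 libraries. NEAT1 lay at 2.47% to 2.69% in untreated and at 3.34% to 3.39% in irradiated iCLIP libraries, while the MALAT1 means were 1.39% and 1.35%.

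The RNAs of TIRR and of its partner were sparse in the iCLIP libraries. NUDT16L1 had 25 and 32 counts in the untreated and 19 and 42 in the irradiated libraries, a log2 fold change of 0.72 ± 0.28 (SE, edgeR adjusted p = 0.213). TP53BP1 had 91 and 94 counts before and 64 and 99 after irradiation, a log2 fold change of 0.46 ± 0.18 (SE, edgeR adjusted p = 0.213). In RNA-seq NUDT16L1 went from 208 to 184 counts, a ratio of 0.875 (95% counting interval 0.713 to 1.07), and TP53BP1 from 1029 to 1051, a ratio of 1.01 (0.926 to 1.10).

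Across all RNAs, 17 of 22 tested p53 target genes rose in the TIRR iCLIP counts after irradiation and 6 of 23 genes of G2 phase and mitosis fell. Both lists passed limma camera at its preset correlation, but neither did with an estimated correlation (adjusted p = 0.111 for both). FDXR, a mitochondrial ferredoxin reductase, rose 8.97-fold, from 179.8 ± 11.01 to 1611 ± 104 CPM (counts scaled to library size, mean ± SD, n = 2 each, edgeR adjusted p = 8.08e-11). CDKN1A, which encodes the cell cycle inhibitor p21, rose 7.63-fold, from 33.9 ± 10.8 to 259.7 ± 7.11 (edgeR adjusted p = 9.6e-08). BBC3, which encodes the apoptosis inducer PUMA, rose 7.28-fold, from 63.7 ± 12.5 to 464 ± 5.50 (edgeR adjusted p = 7.61e-09). In the other direction AURKA, the mitotic Aurora A kinase, fell to 0.230 of its untreated level, from 58.7 ± 0.154 to 12.3 ± 6.44 CPM (edgeR adjusted p = 0.00168), and CDCA8, a subunit of the chromosomal passenger complex, fell to 0.184, from 42.7 ± 6.86 to 7.68 ± 0.0469 (edgeR adjusted p = 0.00252).

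The largest other rises were those of GRIN2C, a glutamate receptor subunit gene, 8.25-fold, of the inositol phosphatase gene INPP5D, 7.49-fold, and of the death receptor gene FAS, 6.20-fold. GRIN2C ends 964 bases from FDXR on chromosome 17. The long noncoding RNA LINC01411 rose 5.90-fold and INKA2 5.89-fold. PINCR, a long noncoding RNA induced by p53, had 3 counts in both untreated libraries together and 29 in the irradiated ones, a ratio of 15.0 (95% counting interval 4.66 to 77.0). The tenth gene of this group has a clone identifier, and its rise rested on 1 irradiated library, with 274 counts against 23 in the other. PIF1, a DNA helicase gene, went from 103 counts in the untreated libraries to 3 in the irradiated ones, 22.1-fold lower (95% counting interval 7.35 to 109). PSRC1, a spindle protein gene, and CDKN3, a phosphatase gene of the cell cycle, each went from 31 counts to 2, a ratio of 9.98 (2.54 to 86.0). BORA, an activator of Aurora A, had a log2 fold change of -2.18, the spindle pole gene ASPM -1.81, the cytoskeleton gene GAS2L3 -1.79 and SGO2, a protector of centromere cohesion, -1.74. A gene with a clone identifier completes the 10 largest falls.

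In all, 323 of 9230 tested genes changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), 224 upward and 99 downward. Of these, 111 rose and 30 fell at least 2-fold, and 1340 genes had an unadjusted p below 0.05. The groups did not overlap in 223 of the rises and in all 99 falls, and in 44.0% of all tested genes, where chance alone gives 33.3%. Scaled by library totals, 184 genes rose and 132 fell, so that 58.2% of the calls were rises, against 69.3% here. DESeq2 called 122 genes, and without untreated library 1 edgeR called 186. With 1 library left out the calls ended for FAS (without irradiated 2, edgeR adjusted p = 0.0794), for BORA (without untreated 2, 0.267, and without irradiated 1, 0.0510), for ASPM (without untreated 2, 0.0982, and without irradiated 2, 0.0831) and for SGO2 (without untreated 2, 0.0510, and without irradiated 2, 0.251). PSRC1 and CDKN3 lost their calls without untreated 1 (edgeR adjusted p = 0.456 and 0.238), untreated 2 (0.152 and 0.315) or irradiated 1 (0.0951 for both), and GAS2L3 when all libraries were thinned to equal depth (0.273). The risen clone lost its call without irradiated 1 (edgeR adjusted p = 0.371), and the fallen clone had adjusted p values of 0.0661 to 0.521 with any 1 library left out.

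Of 22 tested p53 target genes, 17 rose in the TIRR iCLIP libraries, or 20 when adjusted over the list alone, and the median gene rose 3.35-fold. This list had the smallest p of the 19 lists (limma camera adjusted p = 1.66e-75, but adjusted p = 0.111 with an estimated correlation). Besides FDXR and BBC3 it held MDM2, the ubiquitin ligase that restrains p53, which rose 5.15-fold, BLOC1S2, 4.34-fold, FBXO22, 2.53-fold, and the apoptosis gene BAX, 2.05-fold (edgeR adjusted p = 9.6e-08, 1.51e-06, 0.000113 and 0.0170). BAX lost its call without irradiated library 2 (edgeR adjusted p = 0.535), with thinning to equal depth (0.0509) and in DESeq2 (0.0916). Only CCNG2 of the 22 had a negative log2 fold change, -0.26 (edgeR adjusted p = 0.580). Of 23 tested genes of G2 phase and mitosis, 6 fell, or 14 when adjusted over the list alone, and all 23 had a negative log2 fold change with a median of -0.96 (limma camera adjusted p = 1.16e-15, but adjusted p = 0.111 with an estimated correlation). Among its members with the most counts were TPX2, a spindle assembly factor, with a log2 fold change of -1.10 (edgeR adjusted p = 0.0240), ANLN with -0.63 (0.0725), HJURP with -0.66 (0.266) and ECT2 with -0.50 (0.418). ANLN gained a call with library totals (log2 fold change -0.70, edgeR adjusted p = 0.0463) and without irradiated 1 (-0.78, 0.0139). TPX2 lost its call without untreated 2 (edgeR adjusted p = 0.259), without irradiated 2 (0.0543), with thinning to equal depth (0.0506) and in DESeq2 (0.199).

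The spliceosomal small nuclear RNA genes and their copies moved upward as a list, with a median log2 fold change of 0.38 over 27 tested members, of which 3 rose, or 5 when adjusted over the list alone (limma camera adjusted p = 0.00443, but adjusted p = 0.397 with an estimated correlation and 0.294 with no filter on low counts). RNU1-67P, the member with the most counts, had a log2 fold change of 0.45 ± 0.13 (SE, edgeR adjusted p = 0.0808) and passed without irradiated 2 (0.55, 0.0134). RNU6-31P and RNU6-222P rose 2.19-fold and 1.89-fold, and both lost their calls without untreated 2 (edgeR adjusted p = 0.0964 and 0.182) or irradiated 2 (0.165 and 0.1998), RNU6-222P also without untreated 1 (0.245), with library totals (0.0655) and with no filter (0.0890). RNVU1-2A had 27 counts in irradiated library 1 and 983 in irradiated library 2, and its log2 fold change was -0.01 without the latter. These genes are near-identical copies, so how reads were split among them is uncertain. The mitochondrial genes also moved upward as a list, with a median of 0.42 over 17 tested members, of which 0 changed, or 1 when adjusted over the list alone (limma camera adjusted p = 0.0132, but adjusted p = 0.401 with an estimated correlation). MT-ND6 had a log2 fold change of 0.44 ± 0.12 (SE, edgeR adjusted p = 0.0521), MT-ND5 0.41 ± 0.21 (0.395), MT-RNR1 0.26 ± 0.20 (0.626) and MT-RNR2 0.13 ± 0.23 (0.874). MT-ND6 gained a call with the stricter filter (edgeR adjusted p = 0.0397) and without irradiated 1 (0.00722). MT-RNR2 passed upward without untreated 2 (0.57, edgeR adjusted p = 0.00437) or irradiated 2 (0.56, 7e-06) and downward without irradiated 1 (-0.47, 0.000404). The list's share of the gene counts was 0.613% and 0.959% in the untreated and 1.08% and 0.629% in the irradiated libraries, and its call ended without untreated 1 (limma camera adjusted p = 0.0958), without irradiated 1 (0.196) and with thinning to equal depth (0.103).

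Of 22 nuclear long noncoding RNAs tested, 3 rose: NEAT1, PVT1 by 1.65-fold and PURPL, a regulator of p53 levels, by 2.84-fold (edgeR adjusted p = 0.00271, 0.000312 and 1.47e-05). MIAT had a log2 fold change of -0.21 (edgeR adjusted p = 0.487) and passed without irradiated 2 (-0.41, 0.0395). The list as a whole did not pass (median 0.02, limma camera adjusted p = 0.369). Among 31 genes of double-strand break repair 1 passed, the ligase gene LIG4, 1.60-fold (edgeR adjusted p = 0.0350), and the list did not (median 0.03, mean -0.01 and test direction down, limma camera adjusted p = 0.949). LIG4 lost its call with library totals (edgeR adjusted p = 0.0662), without untreated 2 (0.447), without irradiated 2 (0.0911) and in DESeq2 (0.255). The paraspeckle proteins had a median of 0.01 and a mean of -0.01 over 23 genes (limma camera adjusted p = 0.949, direction down). The remaining lists did not pass either (limma camera adjusted p from 0.189 to 0.860). Under other settings some lists passed upward: with no filter on low counts the immediate early genes (limma camera adjusted p = 0.00959) and the NF-kB target genes (0.0220), the small nucleolar RNAs without untreated 2 (0.00704) or irradiated 2 (0.000421), and the nuclear long noncoding RNAs without irradiated 1 (0.0392). Their median log2 fold changes were 0.50 for immediate early genes, 0.29 for NF-kB target genes, 0.29 for small nucleolar RNAs, 0.26 for the NUDIX family with NUDT16L1 and 0.16 for SNHG host genes. They were 0.13 for ribosomal protein genes, 0.10 for S phase genes, 0.09 for unfolded protein response genes, 0.04 for osteoblast and mesenchymal markers (test direction down), -0.02 for translation factors (mean 0.00145), -0.09 for splicing factors and -0.15 for cholesterol synthesis genes.

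RNA-seq addressed which genes' expression the dose changed, with 1 library per condition and therefore no test. The p53 target genes were higher and the mitotic genes lower in the irradiated library. CDKN1A had 2335 counts before and 8111 after irradiation, a ratio of 3.43 (95% counting interval 3.28 to 3.60), MDM2 had a ratio of 3.59 (3.34 to 3.86), the antiproliferative gene BTG2 3.91 (3.56 to 4.31) and FAS 3.84 (3.38 to 4.38). PLK1, the Polo-like kinase of mitosis, had 2542 and 619 counts, 4.15-fold lower, and the kinesin gene KIF20A had 1828 and 427 counts, 4.33-fold lower.

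Among 12977 genes with at least 100 counts in either library, 112 were higher and 81 lower by at least 2-fold with a counting interval beyond 1.5-fold. The largest rises were in KLLN, a p53-regulated gene, with 13 and 113 counts and a ratio of 8.60 (4.83 to 16.6), and in the adhesion gene NECTIN4, 8.35 (5.90 to 12.1). They were followed by the stress transcription factor gene ATF3 with 4.48 (3.63 to 5.57), the riboflavin transporter gene SLC52A1 with 4.37, the cytokine gene GDF15 with 4.32, the ceramidase gene ACER2 with 4.20, DNAI3 with 4.19, the apoptosis inhibitor gene BIRC3 with 4.09 and ZNF423 with 3.59. PIF1 had 406 counts before and 49 after irradiation, 8.38-fold lower, and TOX3 was 5.38-fold lower. The growth factor response genes FOS and EGR1 were 4.42-fold and 3.66-fold lower, UBALD2 3.43-fold, TNFAIP8L1 3.41-fold, the centrosome kinase gene NEK2 3.29-fold and the stem cell transcription factor gene SOX2 3.24-fold. The other 2 of the 12 largest falls have clone identifiers. Of the 193 genes, 174 have a known position, and 51 of the higher and 35 of the lower ones overlap another annotated gene, among them FAS, MDM2, KIF20A, PLK1, NECTIN4, NEK2 and SOX2, and the strand setting of the counting is not given in the sources used here. With a minimum of 500 counts, 98 genes passed.

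Of 23 gene lists, 6 had a median log2 ratio outside 95% of random lists matched on expression. The p53 targets had a median ratio of 2.24-fold over 39 genes, 38 of them higher and 26 past the size rule, against a random range of -0.08 to 0.07 on the log2 scale. The genes of G2 phase and mitosis had a median of 0.519 over 39 genes, with 0 higher and 18 past the rule. Among them TOP2A stood at 0.839, ANLN at 0.767, TPX2 at 0.485 and CCNB1, the mitotic cyclin, at 0.476. The replication-dependent histone genes had a median of 0.713 over 18 genes, with H2BC12 at 1167 and 900 counts and H1-2 at 612 and 617. The NF-kB target genes had a median of 1.53-fold over 17 genes, with BIRC3, CSF1 at 2.79-fold and RELB at 2.28-fold past the rule, and LIF at 1.65-fold and NFKB2 at 1.10-fold. The mitochondrial genes had a median of 0.769 over 31 genes, and their share of the gene counts went from 5.27% to 4.15%. MT-CO1 stood at 0.757, MT-CO2 at 0.769 and MT-ND4 at 0.705, but MT-RNR2 at 0.982. The cholesterol synthesis genes had a median of 0.845 over 19 genes with 0 higher, among them SQLE at 0.687, FDFT1 at 0.792 and SREBF2 at 0.921.

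The other 17 lists lay inside the random range. Immediate early genes had a median log2 ratio of -0.08, with ATF3 and DUSP1 past the rule upward and FOS and EGR1 downward. Double-strand break repair genes had 0.00, paraspeckle proteins -0.01, nuclear long noncoding RNAs 0.00, S phase genes -0.06, SNHG host genes -0.07, small nucleolar RNAs 0.05, interferon-stimulated genes 0.02, ribosomal protein genes 0.00, translation factors 0.05, splicing factors 0.03, the NUDIX family -0.06 and unfolded protein response genes 0.04. Marker genes of epithelial, haematopoietic and endothelial cells had medians of -0.17, 0.08 and 0.18, and osteoblast and mesenchymal markers 0.09.

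Set against RNA-seq counts in untreated cells, the TIRR iCLIP counts were high on most of the listed nuclear long noncoding RNAs. They were low on mitochondrial and ribosomal protein mRNAs. No background library was analysed, and how evenly RNA-seq recovered these RNAs was not measured. These ratios alone therefore do not show a preference of TIRR. NEAT1 took a 77.9-fold larger share of the iCLIP counts than of the RNA-seq counts (log2 ratio 6.28 ± 0.09, SD over 2 iCLIP libraries), rank 16 of 11385 genes, and MALAT1 an 80.4-fold larger share (6.33 ± 0.01), rank 14. The nuclear long noncoding RNAs as a list had a median ratio of 4.19-fold over 21 genes, percentile 100 among random lists matched on expression and length. Of the 21 genes, 14 had a larger share in iCLIP than in RNA-seq. PVT1 stood at 90.3-fold and MIAT had a log2 ratio of 4.57. Ribosomal protein genes had a median log2 ratio of -4.58 over 70 genes, percentile 0.39, with RPL4 at -5.51, RPS2 at -5.48, RPLP1 at -6.90 and RPLP0 at -7.65. Mitochondrial genes had -6.38 over 21 genes, percentile 0.01, with MT-CO1 at -8.03, MT-CO2 at -7.68 and MT-ND4 at -6.57, but MT-RNR2 at -0.28.

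Outside the matched range on the high side lay also the SNHG host genes (median log2 ratio 0.52, 20 genes), the splicing factors (-0.72, 31 genes) and the immediate early genes (-0.58, 12 genes). SNHG22 had 3.94, SNHG16 0.60, SNHG14 0.01 and SNHG29 -0.46. Among splicing factors SRRM2 had 0.98, HNRNPA2B1 -1.38, DDX5 -1.67 and HNRNPU -1.71, and among immediate early genes KLF10 had -0.38, JUN -0.44, MCL1 -0.97 and IER5 -3.56. The median for p53 targets was -0.27, for G2 phase and mitosis genes -2.16, for double-strand break repair genes 0.35 and for paraspeckle proteins -0.99 (percentile 97.0), all inside the range. With the irradiated libraries, and random lists drawn anew for them, the p53 targets lay above their range (-0.01 over 26 genes, range -2.24 to -0.63) and the G2 phase and mitosis genes below theirs (-2.08 over 31 genes, range -2.05 to -0.60). Without untreated 2 the paraspeckle proteins lay just above a range drawn anew (-0.9457, range -2.68 to -0.9497, percentile 97.6). NUDT16L1 had a log2 ratio of 1.19 ± 0.22 and TP53BP1 0.57 ± 0.01 (SD over 2 iCLIP libraries). The iCLIP cells held FLAG-tagged TIRR and the RNA-seq cells were wild-type, so the NUDT16L1 counts of the assays may not be comparable. The named genes with the highest ratios were RORA, a nuclear receptor gene, at 168-fold, SMOC2 at 155-fold, MAGI2 at 104-fold, LINC00299 at 103-fold, SPACA6 at 96.1-fold and PVT1. At the low end CALM2, a calmodulin gene, had 4278 RNA-seq counts and 0 in both untreated iCLIP libraries, MIF-AS1, which overlaps MIF (4753 RNA-seq counts), had 4961 and 0 in both, and RHOA, a small GTPase gene, had 8230 and 1 in each. BEST1, which overlaps the ferritin gene FTH1, had 22929 RNA-seq counts against 1 and 2 in iCLIP. The ratio rose with gene length across genes (Spearman rho 0.641, and genes are not independent replicates). Of the genes with over 1000 RNA-seq counts, 20.9% appear in no iCLIP library. They were left out of the ratios, so the ranks, the list medians and the low end do not cover them.

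**Figure D2:**
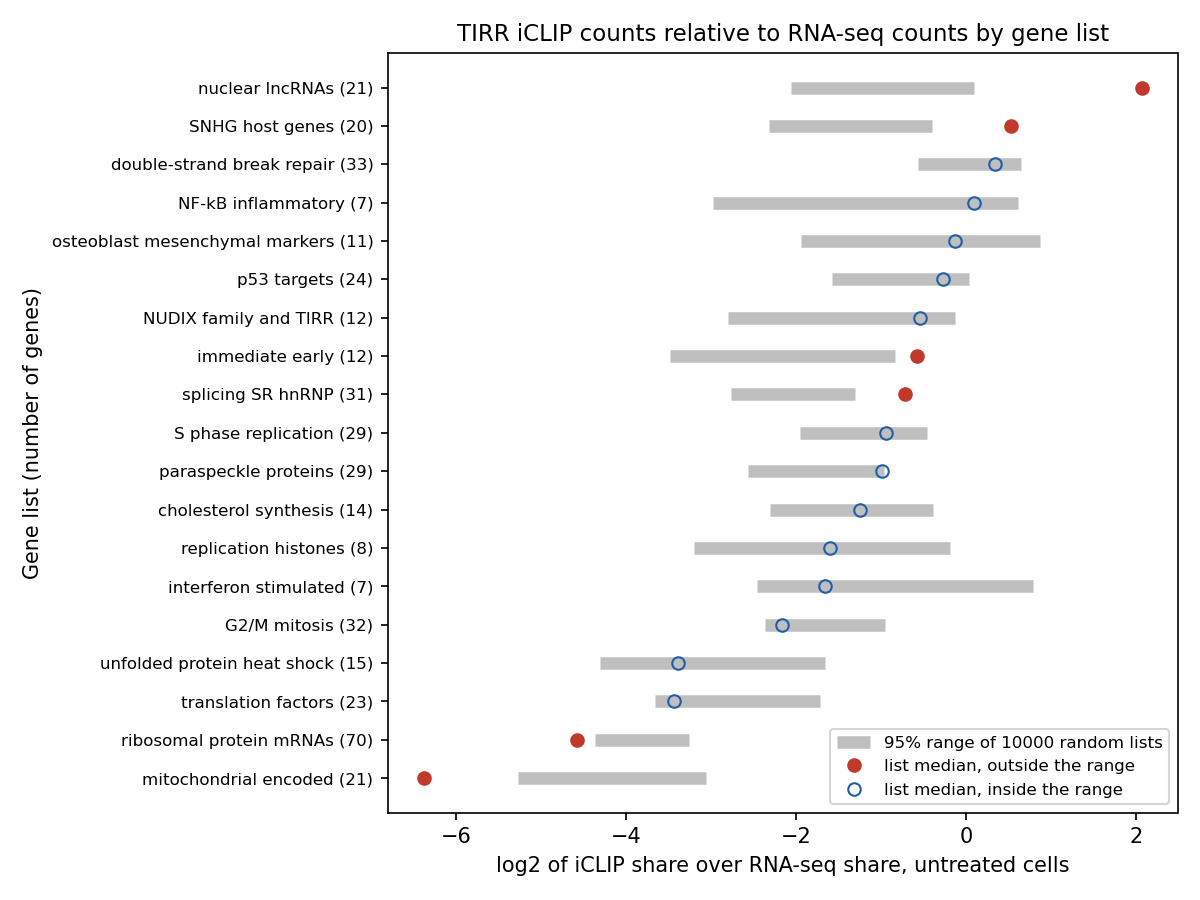
Median log2 ratio of the share of iCLIP counts (mean of 2 untreated libraries) over the share of RNA-seq counts (1 untreated library) for 19 gene lists, with the number of genes in parentheses and grey bars for 95% of 10000 random lists matched on expression and gene length. Nuclear long noncoding RNAs lay highest at 2.07 and mitochondrial genes lowest at -6.38.

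The last comparison set each gene's change in the TIRR iCLIP counts beside its change in RNA-seq. Of the 224 genes that rose in iCLIP, 212 could be set beside RNA-seq, and 176 of these (83.0%) had a higher RNA-seq value after irradiation, with a median log2 change of 0.96 in iCLIP and 0.43 in RNA-seq. Of the 99 that fell, 98 could be compared and 87 (88.8%) had a lower RNA-seq value, with medians of -0.88 and -0.48. NEAT1 was among the genes that rose in iCLIP without a higher RNA-seq value, with 0.45 and -0.20. For genes not called in iCLIP the share with the same sign was 55.1%. Of 58 genes past the RNA-seq rule upward and tested in iCLIP, 37 rose there and 55 had a positive log2 fold change, and of 41 past it downward, 14 fell and 6 had a positive one. The median log2 changes were 1.42 in iCLIP and 1.21 in RNA-seq for the upward group, and -0.87 and -1.24 for the downward group. Neither group held a gene that changed in the opposite direction in iCLIP. Over 8490 genes the changes had a Spearman rho of 0.221 and a Pearson r of 0.325 across genes, which are not independent replicates (permutation p = 1e-05 for both relations, two-sided, adjusted or not the smallest that 100000 permutations can give).

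**Figure D3:**
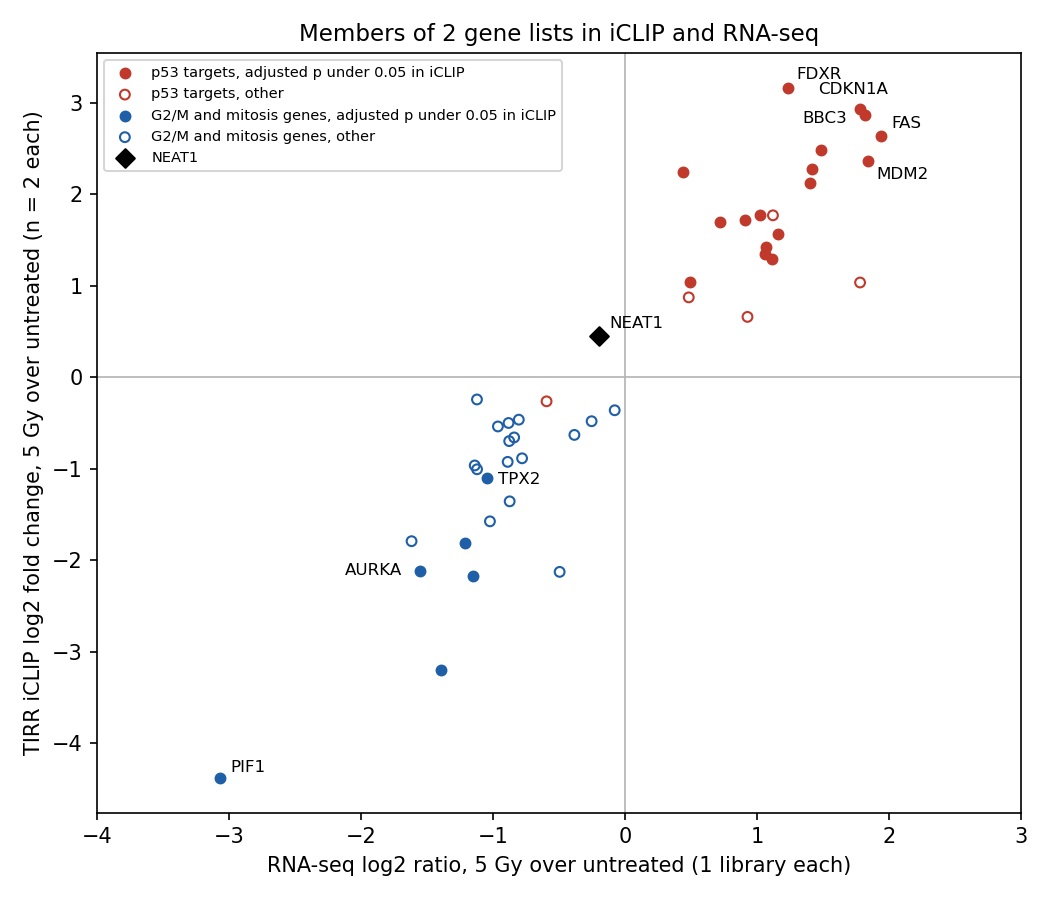
Change after irradiation in TIRR iCLIP (log2 fold change, 2 libraries per group) against RNA-seq (log2 ratio, 1 library per group) for 22 p53 targets, 23 genes of G2 phase and mitosis and NEAT1, with filled points for genes called in iCLIP. NEAT1 lies at 0.45 in iCLIP and -0.20 in RNA-seq, and the fitted value of PIF1 rests on 3 counts in the irradiated libraries.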

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

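The tests of the NEAT1 pattern and the test of genes missing from the iCLIP tables were chosen after the results were seen, and the others before.

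NEAT1 moved in opposite directions in the assays: it rose in both irradiated TIRR iCLIP libraries (log2 fold change 0.45, SE 0.08, edgeR adjusted p = 0.00271, but not called with a replicate block or DESeq2), and its RNA-seq log2 ratio was -0.1971 (95% counting interval -0.26 to -0.13). The difference between the assays was not tested, since RNA-seq had 1 library per condition. Library depth or scaling is argued against, because the NEAT1 to MALAT1 count ratio within a library went from 1.93 and 1.79 to 2.53 and 2.44, a log2 difference of 0.4205 (SE 0.06), and 6 scalings, filters and equal depth kept an edgeR adjusted p of at most 0.0240. More NEAT1 RNA in irradiated cells stays open, because the RNA-seq value points the other way but rests on 1 library per condition, on wild-type cells and perhaps on another radiation source. A larger part of NEAT1 bound by TIRR after irradiation may remain as a hypothesis, and it was not tested here.

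Most genes called in the iCLIP comparison moved the same way in RNA-seq, 263 of 310, or 84.84%. RNA abundance could therefore account for part of these changes, but it cannot be told apart from altered binding here. The median RNA-seq log2 change in the direction of the call was 0.46 against 0.93 in iCLIP, just under the share of 0.5 set in advance. RNA-seq had 1 library per condition, and choosing genes by their iCLIP change can enlarge their iCLIP median. Genes chosen by the RNA-seq size rule had medians of 1.42 in iCLIP and 1.21 in RNA-seq upward, and -0.87 and -1.24 downward. That choice can in turn enlarge the RNA-seq median. Counts spilling over from a called neighbour explain at most a small part. Of 293 called genes with a known position, 20, or 6.83%, overlap or lie within 5 kb of another called gene. Among them are GRIN2C beside FDXR and ACTA2 overlapping FAS. Neighbours that are absent from the iCLIP counts or were filtered out could not be called, so spilling from them was not covered.

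Intergenic counts, which no comparison used, made up 30.6% and 30.8% of the untreated and 31.3% and 30.9% of the irradiated iCLIP libraries, and 44.4% of each RNA-seq library (44.3817% untreated, 44.3594% irradiated). Genes missing from the iCLIP counting annotation are a candidate explanation for part of this in iCLIP: 20.85% of the 6167 genes with over 1000 RNA-seq counts have no iCLIP count in the tables used here, among them COL1A1, FLNA, SPARC and YBX1, but only 219 have 1 to 5 counts, and the intergenic length is 177.5 Mb larger in the iCLIP tables. An RNA-seq library without strand that was counted by strand may add to the intergenic share in RNA-seq, since counts of 771 genes and their antisense genes had a Spearman rho of 0.330 across pairs in RNA-seq and -0.122 in iCLIP. No biological explanation was tested for the intergenic share.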

How the results depend on the processing

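The thinning to equal depth and the removal of overlapping RNA-seq genes were chosen after the results were seen. Of the values for single results under the alternatives, 950 were counted as unchanged, with no call lost or gained. A list or RNA-seq gene without a call may have changed sign among these. Of the others, 65 lost a call, 18 gained one, 9 turned and 1 moved, and 45 of the 54 values of the main results stayed. Genes changed in iCLIP numbered 311 to 353 with other scalings, filters and without multicopy RNAs and 256 after thinning, but 122 with DESeq2 (105 rose, all 122 shared), which gave an adjusted p to fewer genes (3683), and 186 to 421 with 1 library left out, where the lone library is assumed to vary like the other group. NEAT1 kept its rise at 0.38 to 0.51 with 1 library left out, and DESeq2 gave 0.45 (adjusted p = 0.0742); the cause was not tested. A fit with a replicate block called 190 genes, all among the 323, and gave NEAT1 0.45 (edgeR adjusted p = 0.252). The labels give no meaning to the replicate numbers, and same-numbered libraries did not deviate together (correlation -0.0993). Among named genes the block also ended the calls of PSRC1 (adjusted p = 0.0575), OSBPL10 (0.195), LIG4 (0.0792), RNU6-222P (0.109), MAP2K6, ARHGAP33 and 1 clone, and it changed no other call of the genes reported here. Called lists numbered 2 without multicopy RNAs, which removes the small nuclear and mitochondrial lists, 0 with an estimated correlation, 5 with no filter, 3 after thinning, 3 with fry, which adds the ribosomal protein genes (adjusted p = 0.0213), and 3 to 5 with 1 library left out. RNA-seq genes past the size rule numbered 98 with a minimum of 500 counts and 88 without genes that overlap another or have no known position (174 of the 193 have one), as fewer genes are counted, and 192 to 279 otherwise. MALAT1 turned to -0.036 with library totals and -0.0053 with no filter, and FAM95A to -0.0011 with library totals. With 1 library left out the log2 fold changes ranged from -0.026 to 0.15 for FAM95A, from -0.47 to 0.57 for MT-RNR2, from -0.073 to 0.60 for MT-RNR1, from -0.24 to 0.61 for RNU1-138P and from -0.0061 to 4.43 for RNVU1-2A; the cause was not tested. The correlation of iCLIP change against RNA-seq change across genes was 0.169 to 0.249. In the self-test 42.2% of simulated 2-fold falls were called, so falls of that size are often missed at this depth.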

Other observations

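The values in this part were chosen after the results were seen.

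Several genes changed in the TIRR iCLIP counts while their RNA-seq counts stayed nearly level. Of 166 called genes with at least 500 counts in an RNA-seq library, 36 had an RNA-seq ratio within 1.1-fold, and 28 of these rose in iCLIP while 8 fell. Among those with the most iCLIP counts, ACTN1, which encodes the actin crosslinker alpha-actinin, had a log2 fold change of 0.83 in iCLIP and a log2 ratio of 0.07 in RNA-seq. The splicing factor gene SRSF5 had 0.56 and 0.02, the kinase gene MAP4K4 0.73 and -0.00, RNF213 0.66 and 0.01, and CIC, a transcriptional repressor gene, 0.87 and -0.02. On the other side NTM had -0.65 and -0.05, the tropomyosin gene TPM1 -0.95 and 0.09, and the matrix protease gene MMP2 -1.08 and -0.09. Each RNA-seq value rests on 1 library per condition.

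Long genes were over-represented among the falls in iCLIP. Among the longest 10% of tested genes (median 468 kb) 37 genes fell and 16 rose, while among the shortest 10% (median 6.26 kb) 3 fell and 17 rose. The median log2 fold change was -0.09 in the longest and 0.11 in the shortest group. The RNA-seq medians, here taken without TMM scaling, were 0.03 over the 729 of 923 longest and -0.06 over the 786 of 923 shortest genes that could be set beside RNA-seq. Among genes outside the longest group, 62 fell and 208 rose. With library totals 49 of the longest genes fell and 12 rose, and with 1 library left out the falls numbered 12 to 41 and the rises 8 to 19. The 37 fallen long genes had a median of -0.70 in iCLIP and -0.28 in RNA-seq, again without TMM scaling, and 28 of them had a lower RNA-seq value. Genes are not independent replicates, and no explanation was tested.

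The overlapping long noncoding transcripts LNCTAM34A and MIR34AHG, which lie at the gene of the microRNA miR-34a, had log2 fold changes of 2.52 and 1.76 (edgeR adjusted p = 0.000807 and 2.74e-05) and RNA-seq log2 ratios of 1.54 and 1.19. The share of spliceosomal small nuclear RNAs was 0.208% and 0.218% in the untreated and 0.282% and 0.379% in the irradiated libraries, and 0.201%, 0.211%, 0.276% and 0.231% without RNVU1-2A.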
